A study of Mus musculus with 9 samples.

How the data were processed

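RNA-seq libraries were made from nestin-reporter cells that were sorted by green fluorescence from the dissected dentate gyrus (DG, n = 5) or subventricular zone (SVZ, n = 4) of adult mice. Per the labels' protocols, cDNA was made from total RNA with a poly-dT primer and template switching, amplified over its full length, sheared and turned into libraries with a kit that does not mark the strand. PCR copies were not tagged with molecular identifiers, so all intervals on reads cover counting error only. Per the submitters' processing notes, the authors used STAR, edgeR and the mm10 build; versions, the gene counter, the annotation release and the low-count filter are not given in the sources used here.

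The deposited table holds 14477 genes in 9 columns, each of which matched 1 sample by the library number in its title. Although the table is described as counts, its values are not whole. They are log2 CPM as deposited by the authors, with a prior count of 1 read scaled to each library and no scaling beyond the library totals, as inferred from the values: this formula gave back every deposited value within 5.33e-14. Reads recovered with it were whole numbers for 100% of values (tolerance 0.001, largest distance 1.09e-08). A fold change is therefore on a log2 scale with a prior count, which understates the change of genes with few reads. Each gene of the table exceeded 1 CPM in at least 3 libraries, and 14296 genes had reads in all 9. Recovered totals ranged from 31126803 to 41164044 reads per library, and 1 read was worth 0.0243 to 0.0321 CPM. The totals cover the genes of the table alone. Deposited samples of the same group were compared for duplicates by a chi-square test of their reads, and all pairs differed by more than sampling noise (chi-square per degree of freedom 19.6 to 173).

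The design fixed before the data were examined planned a count test, with limma on log2 values if the table was not raw counts. Since the deposited unit is log2, the test was limma 3.58.1 (R 4.3.3), with a mean-variance trend, on the deposited values, with tissue as the only term and DG minus SVZ as the contrast. All 14477 genes were tested without a further filter, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Every adjusted p of a gene is from this fit. All 9 libraries gave a group and none was left out.

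The 30 gene lists tested were fixed with the design and had at least 5 measured members. They cover the lineages of the 2 regions, other cell types that the sort could hold, the cell cycle, oxidative metabolism and signalling. Lists were tested with camera (limma, preset correlation of 0.01 between genes), which compares a list with all other genes, and again with the correlation estimated for each list. The rotation test fry asked whether the genes of a list moved one way on balance. Adjustment was over the lists. Member counts were also adjusted over the list alone. Of 870 list names, 2 (Cyr61 and Sfrp3) matched no symbol. The medians of the dorsal, fibroblast and NADPH oxidase lists were unchanged to 3 digits (2.89, 4.72 and 0.895) when the member with 1 to 3 reads over all SVZ libraries was set to its bound. List medians carry 95% bootstrap intervals over genes (5000 draws) where an interval is given.

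Named genes followed a rule fixed in advance. It took the 12 genes with the largest fold change in each direction, among genes past the threshold with a mean of at least 3 log2 CPM, without overlap between the groups and with a symbol that is not a clone, predicted-gene or pseudogene name. To these it added up to 2 members per direction of each list with the smallest adjusted p, and Nes, Gfap, Sox2, Egfr, Mki67, Dcx, Dlx2, Eomes, Neurod1, Prox1, Emx1, Lpar1 and Aldoc whatever their result, 131 genes in all. Other list members are named as examples, and some genes that the rule takes are not reported here.

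Library totals, genes with at least 1 read, the share of the 100 most abundant genes and the share of mitochondrially encoded genes were compared with exact two-sided permutation tests over all splits of the 9 libraries, adjusted over the 4 measures. Similarity was the Pearson correlation of log2 CPM over all genes, with principal components of the same values. Symbols, coordinates (1-based) and exon overlaps came from GENCODE M21, which annotates the build the notes name. Of the identifiers, 14428 matched a symbol and 49 did not.

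Before use, the fit was tested on simulated reads for the same 14477 genes, with means and totals of the real libraries and 200 changed genes. It recovered 16.4% of 67 genes changed 1.5-fold, 53.7% of 67 changed 2-fold and 87.9% of 66 changed 4-fold, with 5 false calls. The raised and the lowered list were called, and 0 of 28 unchanged lists were. The simulated genes varied independently, so this does not show how the list test behaves where genes vary together. The share recovered depends on how many genes change. In the real fit 66.6% of genes were called, so the shares recovered here do not carry over to it. A gene that did not pass may still differ by a small fold.

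Alternatives planned in advance were limma-voom on the recovered reads, RLE scaling, a stricter filter (5 CPM in at least 4 libraries, 11471 genes), a robust fit, the replicate number as a block, a threshold of 0.01, a minimum log2 fold change of 1, and leaving out each library in turn. Chosen after seeing the data were TMM scaling, prior counts of 0.5 and 5, a fit without the trend, other settings of the similarity, and leaving out DG 2, DG 3 and SVZ 1 together. The check of pairing is given with the effect of the alternatives. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.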

Results

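RNA was sequenced from adult mouse neural precursor cells of 2 brain regions, the dentate gyrus of the hippocampus (DG) and the subventricular zone of the lateral ventricle (SVZ). Both are sites where neurons are made in adulthood: DG precursors give rise to glutamatergic granule cells, and SVZ precursors give rise mainly to GABAergic interneurons of the olfactory bulb. The mice carried a transgene in which regulatory sequence of Nestin, a gene of neural stem and precursor cells, drives green fluorescent protein, and fluorescent cells were sorted from each dissected region. The 9 libraries comprised 5 from the DG and 4 from the SVZ, all from untreated mice in standard housing. Total reads over the 14477 genes of the table ranged from 33627909 to 41164044 in the DG libraries and from 31126803 to 32528255 in the SVZ libraries. The labels do not say whether libraries came from separate animals or from pools, and p-values measure only the spread between these libraries, part of which may be technical. In 6 of the 9 libraries the X inactivation transcript Xist and the Y-linked gene Ddx3y were both present, as in DG 1 at 5.01 and 5.81 log2 CPM. The comparison asked how cells sorted with the same reporter differed in expression between the regions. Expression is given as log2 CPM, reads scaled to a common library total, with a prior count of 1 read, as mean ± SD over n = 5 DG and n = 4 SVZ libraries, and log2 fold changes are DG minus SVZ with their standard error (SE).

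Among well-expressed genes (mean of at least 3 log2 CPM) without overlap between the groups, most of those with the largest differences belonged to blood vessel walls in DG and to the ventral, GABAergic lineage in SVZ. Of the 12 with the largest increase in DG, 7 were members of the list of pericyte and smooth muscle genes, the cells that wrap capillaries and larger vessels. Vtn (ENSMUSG00000017344, chromosome 11, 78499091 to 78502324, plus strand), which encodes the adhesion protein vitronectin, stood at 12.04 ± 0.48 in DG and 4.85 ± 0.70 in SVZ, a 146-fold difference (log2 fold change 7.19, SE 0.32, adjusted p = 2.85e-08). Anpep, an aminopeptidase of pericytes, was 183-fold higher in DG (7.51, SE 0.42, adjusted p = 1.03e-07), and Rgs5, a regulator of G protein signalling in pericytes, was 138-fold higher. The potassium channel genes Kcnj8 and Abcc9, which together encode a channel of pericytes, were higher by 7.34 and 7.40. Atp13a5 (7.37) and Higd1b (7.18) were the other list members. Outside the list, Enpep (7.36), Slc6a20a (7.27), Slc22a8 (7.07) and Aspn (7.04) were among the 12.

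In the opposite direction, 8 of the 12 well-expressed genes with the largest increase in SVZ were members of the ventral and GABAergic list. Dlx6os1 (ENSMUSG00000090063, chromosome 6, 6820189 to 6871592, minus strand), a long noncoding RNA at the locus of the Dlx homeobox genes, stood at 4.68 ± 2.21 in DG and 10.98 ± 0.18 in SVZ, a 79.3-fold difference (log2 fold change -6.31, SE 0.90, adjusted p = 9.15e-05). The transcription factor genes Sp9, Dlx1 (ENSMUSG00000041911, chromosome 2, 71528113 to 71533981), Dlx5, Meis2 and Sp8 were lower in DG by log2 fold changes of -6.20, -5.88, -5.85, -5.62 and -5.39, and Gad2, a GABA-synthesising enzyme, by -5.54. Outside the list, Chodl, Tiam2, Pbx3 and Prokr2, a receptor that guides neuroblasts to the olfactory bulb, had values of -5.06, -5.03, -4.64 and -4.41, and Foxp2, a list member, -4.67. Dlx2, a list member whose mean level was too low for the 12, differed by -6.22 (SE 0.76, adjusted p = 2.95e-05). The spread of these genes in DG came from library DG 2, in which they were closer to the SVZ level. Without DG 2 the difference grew to 157-fold for Dlx6os1, 138-fold for Sp9, 130-fold for Dlx2, 108-fold for Dlx5, 100-fold for Dlx1, 83.1-fold for Meis2, 80.1-fold for Gad2 and 66-fold for Sp8. For Chodl, Tiam2, Foxp2, Pbx3 and Prokr2 it grew to 56.2-fold, 52.1-fold, 43.2-fold, 41.8-fold and 35-fold.

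Most of the measured transcriptome differed between the regions. Of 14477 genes, 4769 were higher in DG, 4873 were higher in SVZ and 4835 did not pass the test (limma, adjusted p under 0.05). Larger differences lay more often on the DG side, with 554 called genes at 16-fold or more higher in DG and 67 at 16-fold or more higher in SVZ. In 4296 genes every DG library lay above every SVZ library and in 4101 every DG library lay below, together 58% of genes where chance gives 1.59%. The median log2 fold change of all genes was -0.075, and TMM scaling moved it to -0.02. Across genes, Pearson correlations of log2 CPM were 0.956 to 0.985 between DG libraries, 0.97 to 0.985 between SVZ libraries and 0.746 to 0.83 between a DG and an SVZ library. Genes are not independent replicates, and these correlations were not tested. The first principal component separated the regions and held 82.9% of the variance. The second held 3.89% and set library DG 3 (50.77) apart from the other DG libraries (-20.47 to -0.38).

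**Figure D1:**
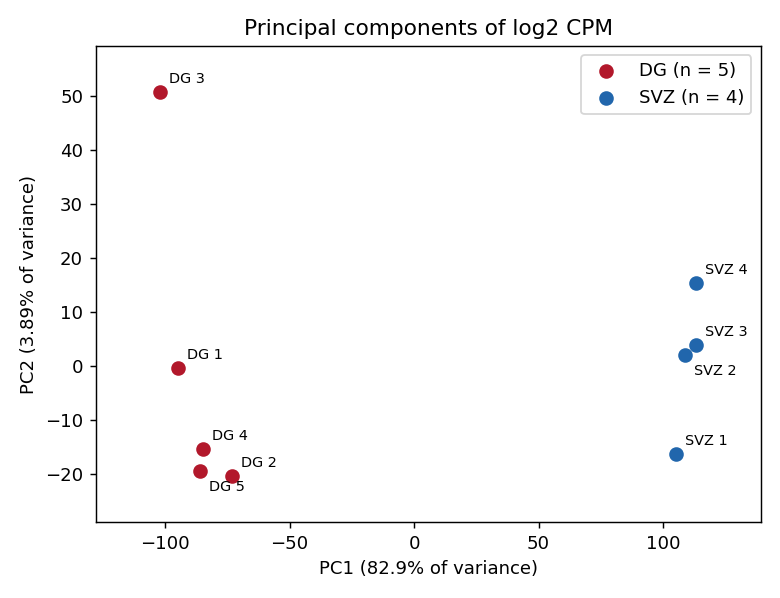
The first 2 principal components of log2 CPM over all genes, 1 point per library, with DG libraries in red and SVZ libraries in blue, and both axes in component units with the share of variance. The first axis (82.9% of variance) parts the regions, and DG 3 stands apart on the second (3.89%).

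The genes that mark the lineage of each region divided between the tissues. Of 32 measured genes of the dorsal telencephalic and glutamatergic granule cell lineage, 25 were higher in DG and 2 in SVZ (median log2 fold change 2.89, camera adjusted p = 1.42e-07, adjusted p = 0.19 with an estimated correlation). Neurod1 (ENSMUSG00000034701, chromosome 2, 79452521 to 79456751), a transcription factor of young granule neurons, was 55.6-fold higher in DG, at 9.25 ± 0.22 against 3.45 ± 0.41 (5.80, SE 0.18, adjusted p = 5.24e-09). Emx1, a homeobox gene of the dorsal telencephalon, was higher by 5.75, and Eomes, which marks intermediate progenitors of glutamatergic neurons, by 3.24. The members higher in SVZ were Nfib (-0.50) and Igfbpl1 (-0.67), and the call of Igfbpl1 was lost without SVZ 1 (adjusted p = 0.0517). Prox1, a transcription factor of granule neurons, did not pass the test, at 7.92 ± 0.19 in DG and 7.81 ± 0.25 in SVZ (0.11, adjusted p = 0.475).

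All 25 measured genes of the ventral and GABAergic list passed the test, 22 of them higher in SVZ and 3 higher in DG (median -4.23, camera adjusted p = 2.12e-05, adjusted p = 0.402 with an estimated correlation). Besides the Dlx and Sp genes, Etv1 was higher in SVZ, with a log2 fold change of -2.31. Members higher in DG included Ebf1 (5.60) and Zic1 (2.40), transcription factors that are also known from other cell types. The list mean was 3.88 in DG 2 and 1.31 to 1.80 in the other DG libraries, and the list median was -4.71 without DG 2.

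Astroglial genes were mostly higher in DG, in libraries whose endothelial and pericyte genes were higher too (medians 5.42 and 5.95). Of 35 genes of radial glia and astroglial stem cells, 27 were higher in DG and 4 in SVZ (27 and 5 adjusted over the list alone), with a median log2 fold change of 1.97 (camera adjusted p = 3.71e-07, adjusted p = 0.22 with an estimated correlation). Gfap (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), the intermediate filament of astrocytes and of stem cells in both regions, was 18-fold higher in DG, at 9.67 ± 0.25 against 5.51 ± 0.59 (4.17, SE 0.24, adjusted p = 1.15e-07). The glutamate transporter gene Slc1a3 was higher by 3.44, the extracellular matrix gene Tnc by 3.34, Aldoc, a glycolytic enzyme of astrocytes, by 3.01 and the lysophosphatidic acid receptor gene Lpar1 by 1.78. Hopx, a marker of quiescent stem cells, was higher by 5.50. Among the members higher in SVZ were Sox2, a stem cell transcription factor (-1.11, SE 0.12, adjusted p = 9.91e-06), Id4 (-0.84) and Nes itself. Nes, the gene whose regulatory sequence drives the reporter (ENSMUSG00000004891, chromosome 3, 87971078 to 87980451), stood at 6.28 ± 0.42 in DG and 7.23 ± 0.34 in SVZ (-0.95, SE 0.22, adjusted p = 0.00238).

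**Figure D2:**
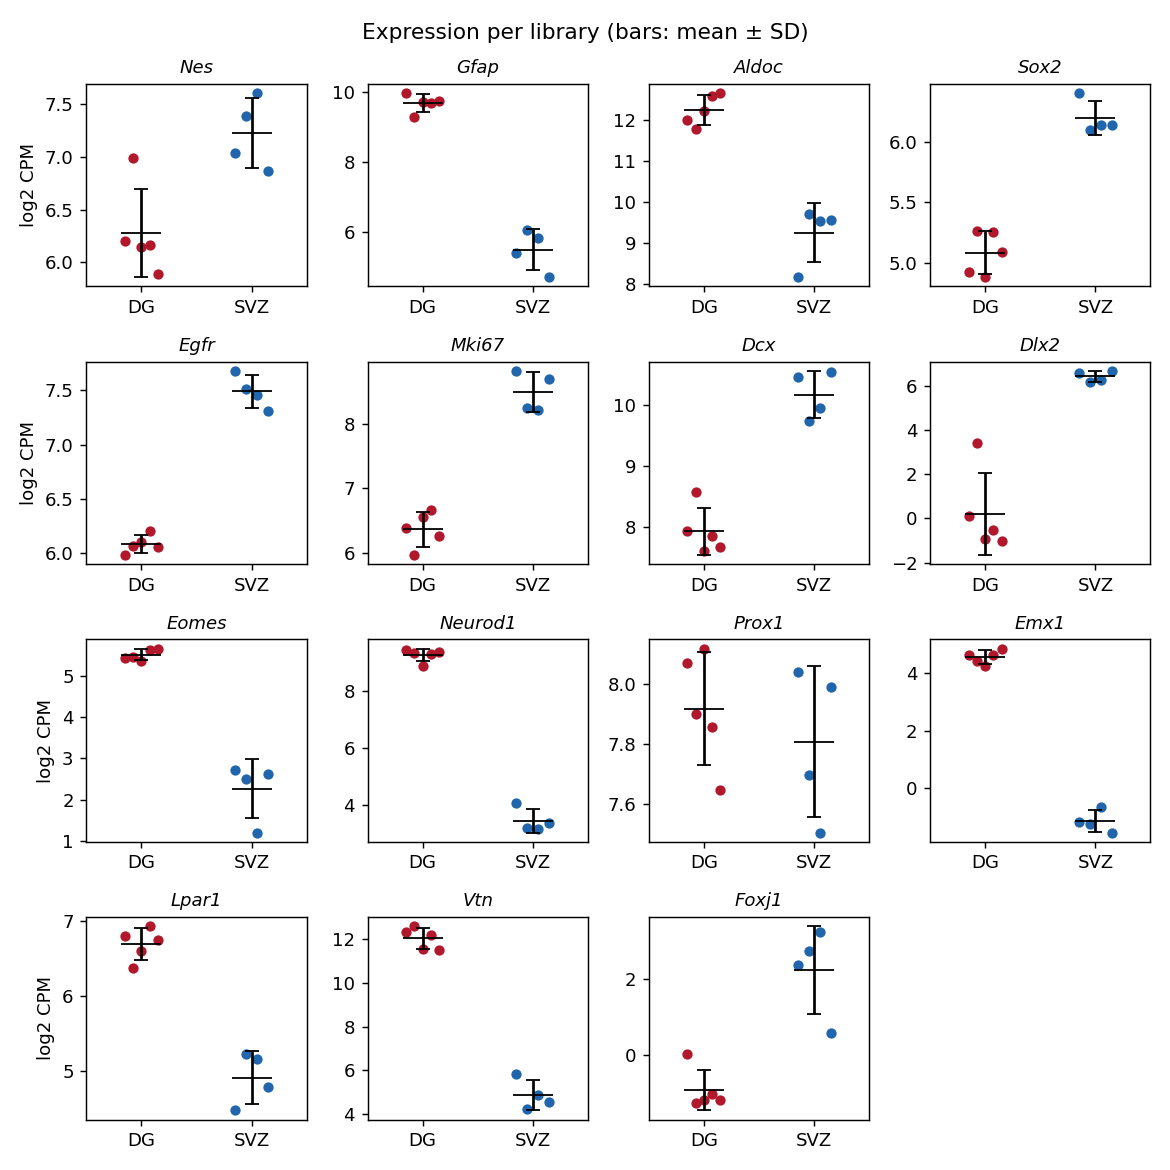
Expression of 15 genes as log2 CPM (vertical axes, which differ between panels and do not start at 0), 1 point per library for the 5 DG and 4 SVZ libraries, with bars for mean ± SD. Gfap, Aldoc, Eomes, Neurod1, Emx1, Lpar1 and Vtn are higher in DG, Sox2, Egfr, Mki67, Dcx, Dlx2 and Foxj1 are higher in SVZ, and 1 DG library (DG 2) lies apart for Nes and Dlx2.

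Proliferation and neuroblast genes were lower in DG, in libraries whose endothelial and pericyte genes were higher (medians 5.42 and 5.95). Of 40 cell cycle genes, 37 were higher in SVZ and 2 in DG (median -1.46, camera adjusted p = 7.12e-12, adjusted p = 0.217 with an estimated correlation). The proliferation marker Mki67 stood at 6.36 ± 0.27 in DG and 8.50 ± 0.31 in SVZ, a 4.4-fold difference (-2.14, SE 0.17, adjusted p = 1.08e-06). Ccnd2, which encodes cyclin D2, differed by -2.88, Rrm2, a subunit of ribonucleotide reductase, by -2.21 and Top2a, a topoisomerase of dividing cells, by -1.84. The 2 members higher in DG were the other D-type cyclin genes, Ccnd1 (0.82) and Ccnd3 (0.73). Egfr, the receptor of a mitogen for activated precursors, was lower in DG by -1.41 (SE 0.09, adjusted p = 3.28e-07). Of 24 migrating neuroblast genes, 22 were higher in SVZ and 0 in DG (median -1.57, camera adjusted p = 2.76e-08, adjusted p = 0.217 with an estimated correlation). Dcx, a microtubule protein of migrating neuroblasts, was 4.74-fold higher in SVZ (-2.24, SE 0.22, adjusted p = 4.79e-06), with Stmn2 at -2.73, Dpysl3 at -1.84 and Sox11 at -1.47. DG 2 had a neuroblast list mean of 8.26, above the other DG libraries at 7.58 to 7.76.

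Ependymal genes, which mark the ciliated lining of the ventricle next to the SVZ, were also higher in SVZ. Of 32 measured members, 30 were higher in SVZ and 0 in DG (median -2.88, camera adjusted p = 4.51e-09, adjusted p = 0.277 with an estimated correlation). The ciliary genes Ccdc153 and Rsph4a were 14.9-fold and 8-fold higher in SVZ, and Foxj1, the transcription factor of motile cilia, differed by -3.15. Mature neuron genes were split, with 12 of 24 higher in DG and 3 in SVZ (median 1.33, camera adjusted p = 0.0292, adjusted p = 0.643 with an estimated correlation). The synaptic vesicle gene Syn2 and the nuclear protein gene Rbfox3 were higher in DG by 2.63 and 2.59, and Syn1 and the GABA receptor gene Gabrb2 were lower, at -1.04 and -1.35. The mean of this list was 5.98 in DG 3 and 3.84 to 4.08 in the other DG libraries, and the list call was lost under the stricter filter on low values (adjusted p = 0.0505).

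Oligodendrocyte lineage genes were mostly higher in DG, beside the higher endothelial and pericyte genes (medians 5.42 and 5.95). Of 20 oligodendrocyte precursor genes, 19 were higher in DG and 1 in SVZ (median 3.55, camera adjusted p = 1.42e-07, adjusted p = 0.22 with an estimated correlation). Cspg4 and Pdgfra, which pericytes and fibroblasts respectively also express, were higher by 5.67 and 4.74, Tmem100 by 4.15, the transcription factor gene Sox10 by 3.34 and the phosphatase gene Ptprz1 by 1.70. Vcan, a matrix proteoglycan, was the member higher in SVZ (-1.08). Of 18 measured mature oligodendrocyte genes, 12 were higher in DG and 1 in SVZ (median 1.53, camera adjusted p = 0.00826, adjusted p = 0.552 with an estimated correlation). Apod was higher by 3.25 and Cryab by 2.40, whereas Mobp, a myelin gene, was lower in DG (-1.65). The SVZ count of this list was 2 without DG 3 and 2 without SVZ 1.

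Genes of blood vessels and their surroundings were higher in DG nearly throughout. All 29 measured endothelial genes passed the test and were higher in DG (median 5.42, camera adjusted p = 7.99e-12, adjusted p = 0.217 with an estimated correlation). Flt1, a receptor of vascular endothelial growth factor, was higher by 6.54, the mucin gene Emcn by 6.37, the tight junction gene Cldn5 by 5.92 and the lipid transporter gene Mfsd2a by 3.95. SVZ 1 had the highest endothelial mean of its group, at 2.50 against 0.94 to 1.11. Without it the median was 6.01, and Flt1 and Cldn5 differed by 7.17 and 6.51. All 19 measured pericyte and smooth muscle genes were higher in DG as well (median 5.95, camera adjusted p = 2.15e-11, adjusted p = 0.217 with an estimated correlation). Pdgfrb, the receptor that recruits pericytes, stood at 10.28 ± 0.59 in DG and 4.47 ± 0.15 in SVZ (5.82, SE 0.25, adjusted p = 2.64e-08). Of 16 fibroblast and meningeal genes, 14 were higher in DG and 1 in SVZ (median 4.72, camera adjusted p = 2.39e-06, adjusted p = 0.217 with an estimated correlation). The transporter gene Slc6a13 was higher by 6.51, the matrix gene Lum by 6.31 and the complement inhibitor gene Serping1 by 3.45, and Fbln1 was lower (-0.91). Other lists also held 1 of the endothelial, 2 of the pericyte and 1 of the fibroblast genes.

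Microglial genes did not move as a group. Of 24 members, 2 were higher in DG, 3 in SVZ and 19 did not pass (2 and 1 adjusted over the list alone), and the list was not called (median 0.35, camera adjusted p = 0.891, adjusted p = 0.971 with an estimated correlation). The 2 members higher in DG were Mrc1 (5.38) and Pf4 (5.53), which are known from macrophages at the borders of the brain. The 3 higher in SVZ were Selplg (-1.92), Tmem119 (-1.43) and P2ry12 (-1.32). Tmem119 lost its call without SVZ 3 or SVZ 4 (adjusted p = 0.0614 and 0.0513), and P2ry12 lost it without DG 2, SVZ 3 or SVZ 4 (adjusted p = 0.0627, 0.0727 and 0.0807). Without SVZ 1 the list median was -0.08, with 2 members higher in DG and 8 in SVZ. Without DG 2 the counts were 8 and 2, without DG 4 they were 3 and 3, without SVZ 3 they were 2 and 1, and without SVZ 4 they were 4 and 1. The choroid plexus list had 7 measured members, of which 1 was higher in DG and 3 in SVZ. It was not called (camera adjusted p = 0.891, adjusted p = 0.966 with an estimated correlation), and its median of 0.03 and mean of -0.22 differed in sign. Enpp2 was higher in DG by 2.01, and Folr1 and Clic6 were higher in SVZ, at -2.33 and -2.30. The DG count of this list was 2 without DG 3 or without DG 4, and its median was -0.52 without SVZ 4.

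**Figure D3:**
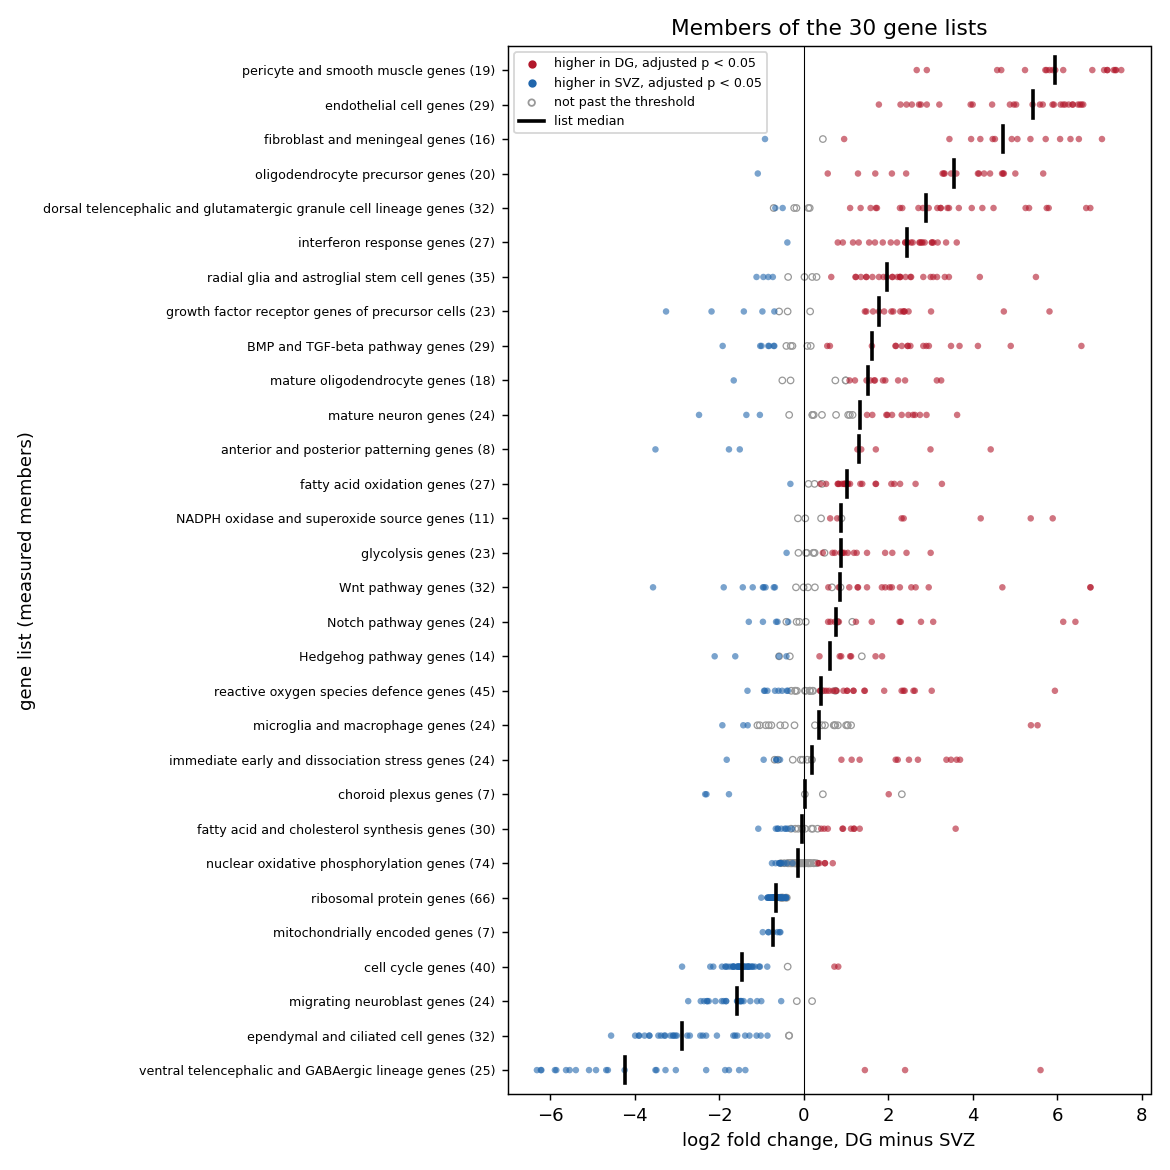
Log2 fold change, DG minus SVZ (horizontal axis), of each measured member of the 30 gene lists (vertical axis, number of members in brackets), with red and blue points for genes called higher in DG or SVZ, open circles for genes not past the threshold and a black bar for the list median. Pericyte (5.95) and endothelial (5.42) medians are the highest and the ventral median (-4.23) is the lowest.

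Genes of oxidative metabolism differed by pathway, in libraries whose endothelial and pericyte list medians differed by 5.42 and 5.95. Of 45 reactive oxygen species defence genes, 23 were higher in DG and 9 in SVZ (25 and 9 adjusted over the list alone; median 0.42, camera adjusted p = 0.0292, adjusted p = 0.542 with an estimated correlation). The cystine transporter gene Slc7a11 was higher in DG by 3.03, the peroxidase gene Gpx8 by 2.60, the extracellular superoxide dismutase gene Sod3 by 5.94 and haem oxygenase Hmox1 by 2.36. Thioredoxin reductase Txnrd1 and peroxiredoxin Prdx2 were higher in SVZ, at -1.33 and -0.92. Among 11 measured genes of NADPH oxidases and other superoxide sources, 7 were higher in DG and 0 in SVZ (median 0.90, camera adjusted p = 0.00866, adjusted p = 0.267 with an estimated correlation). Xanthine dehydrogenase Xdh was higher by 5.89 and Cybb, the catalytic subunit of the phagocyte oxidase, by 4.19, beside the macrophage genes Mrc1 (5.38) and Pf4 (5.53). Nox3, a superoxide-producing oxidase, had 24 to 78 reads in each DG library and 1 read over all SVZ libraries. The ratio of its reads, each group relative to its library totals, was 192, with a 95% exact interval of 34.1 to 7600 that covers counting error only.

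Nuclear genes of oxidative phosphorylation showed little difference, with 5 of 74 higher in DG, 10 in SVZ and 59 not past the threshold (4 and 4 adjusted over the list alone). With all libraries the list was not called (median -0.12, camera adjusted p = 0.298, adjusted p = 0.894 with an estimated correlation). Without DG 5 it was called (adjusted p = 0.0236), with 24 members higher in SVZ. Without SVZ 3 there were 4 such members, and TMM scaling gave 8 and 8. Sdha, a subunit of succinate dehydrogenase, was higher in DG by 0.37, and Ndufs4, a subunit of complex I, was lower (-0.56). All 7 measured mitochondrially encoded genes were lower in DG (median -0.72, camera adjusted p = 0.0211, adjusted p = 0.518 with an estimated correlation), among them mt-Co1 (-0.97) and mt-Nd4 (-0.83). Of 23 measured glycolysis genes, 15 were higher in DG and 1 in SVZ (median 0.87, camera adjusted p = 0.000261, adjusted p = 0.217 with an estimated correlation). Aldoa and Ldha, an aldolase and a lactate dehydrogenase, were higher by 1.93 and 1.26. Gapdh differed by -0.40, a call lost without SVZ 4 (adjusted p = 0.0501).

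As with endothelial and pericyte genes (medians 5.42 and 5.95), fatty acid oxidation genes were higher in DG for 23 of 27 members and in SVZ for 1 (24 and 1 adjusted over the list alone; median 1.02, camera adjusted p = 5.65e-07, adjusted p = 0.217 with an estimated correlation). Cpt1a, the enzyme that controls entry of long-chain fatty acids into mitochondria, was 4.21-fold higher in DG (2.08, SE 0.12, adjusted p = 1.21e-07), and the acyl-CoA synthetase gene Acsl1 was higher by 3.27. The member higher in SVZ, Eci2 (-0.31), lost its call without SVZ 4 and with TMM scaling (adjusted p = 0.0557 and 0.0541). Fatty acid and cholesterol synthesis genes went both ways, 10 of 30 higher in DG and 9 in SVZ (6 without SVZ 1). The list was not called (camera adjusted p = 0.649, adjusted p = 0.867 with an estimated correlation), and its median of -0.04 and mean of 0.23 differed in sign. Thrsp, a regulator of lipid synthesis, was higher in DG by 3.60 and the elongase gene Elovl5 by 1.33. Fdft1, squalene synthase of the cholesterol pathway, was lower (-0.61). Ribosomal protein genes were higher in SVZ for 60 of 66 members and in DG for 0 (0 and 61 adjusted over the list alone; median -0.65, camera adjusted p = 3.63e-07, adjusted p = 0.542 with an estimated correlation). Rps2, a member of this list, was 2-fold higher in SVZ. The count was 40 without SVZ 3 and 47 with TMM scaling, and with that scaling the list median less the median of all genes was -0.57. Their many processed pseudogenes leave the counts of these genes uncertain.

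Signalling lists were mostly higher in DG, as were the endothelial and pericyte lists (medians 5.42 and 5.95), whose cells express several of the same genes. Of 24 Notch pathway genes, 13 were higher in DG and 5 in SVZ (median 0.77, camera adjusted p = 0.0292, adjusted p = 0.267 with an estimated correlation). Heyl and Notch3, an effector and a receptor that pericytes and smooth muscle express, were higher by 6.43 and 6.14 and Hes1, a target of the pathway, by 3.07. Mfng and Rbpj were higher in SVZ, at -0.96 and -0.37. The Notch list was not called without SVZ 2 (adjusted p = 0.0523), and its SVZ count was 3 without SVZ 3. Of 32 Wnt pathway genes, 17 were higher in DG and 9 in SVZ (median 0.85, camera adjusted p = 0.0407, adjusted p = 0.424 with an estimated correlation). Frzb, a secreted Wnt antagonist, was 110-fold higher in DG (6.79, SE 0.17, adjusted p = 1.4e-09) and Tcf7l2, a transcription factor of the pathway, was higher by 2.09. The ligand gene Wnt5a and the receptor gene Fzd5 were higher in SVZ, at -1.44 and -3.56. The Wnt call was lost without DG 4, SVZ 2 or SVZ 3 (adjusted p = 0.0505, 0.0546 and 0.0533) and with TMM scaling (adjusted p = 0.0518).

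Beside the same endothelial and pericyte medians (5.42 and 5.95), BMP and TGF-beta pathway genes were higher in DG for 17 of 29 members and in SVZ for 7 (median 1.61, camera adjusted p = 0.0144, adjusted p = 0.217 with an estimated correlation). The ligand genes Bmp5, Bmp4 and Tgfb2 were higher by 6.57, 4.12 and 3.49, and Id3, a target gene, by 2.83. The signal transducers Smad2 and Smad5 were higher in SVZ, at -1.03 and -0.71. Among 14 Hedgehog pathway genes, 7 were higher in DG and 4 in SVZ (7 and 5 adjusted over the list alone), and the list was not called (median 0.61, camera adjusted p = 0.55, adjusted p = 0.745 with an estimated correlation). Hhip and Boc were higher in DG by 1.86 and 1.70, the target gene Gli1 by 1.12, and Gpr161 and Cdon were lower, at -2.10 and -1.62. Growth factor receptor genes were higher in DG for 15 of 23 members and in SVZ for 5 (median 1.78, camera adjusted p = 0.00676, adjusted p = 0.217 with an estimated correlation). Besides Pdgfrb, Fgfr1 was higher by 2.48, while Erbb4, a neuregulin receptor of migrating neuroblasts, was higher in SVZ (-3.25).

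In the same libraries with higher endothelial and pericyte genes (medians 5.42 and 5.95), interferon response and antigen presentation genes were higher in DG for 26 of 27 members and in SVZ for 1 (median 2.45, camera adjusted p = 1.63e-08, adjusted p = 0.217 with an estimated correlation). The histocompatibility genes H2-K1 and B2m were higher by 2.58 and 2.40, and the interferon-induced genes Irf7 and Isg15 by 3.17 and 2.74, whereas Ifit2 was lower (-0.38). Immediate early and dissociation stress genes were not called as a list (median 0.19, camera adjusted p = 0.298, adjusted p = 0.778 with an estimated correlation), with 11 of 24 higher in DG and 5 in SVZ. Nr4a1 and Ier3 were higher in DG by 3.49 and 2.70, and Egr1, Hsp90aa1 and Jun were higher in SVZ, at -1.82, -0.95 and -0.64. The median of this list was 0.80 without SVZ 3, 0.05 without SVZ 1 and -0.02 without SVZ 4. Of 8 measured genes of anterior and posterior patterning, 5 were higher in DG and 3 in SVZ (median 1.32), and the list was not called (camera adjusted p = 0.326, adjusted p = 0.478 with an estimated correlation). Nr2f2, a caudal telencephalic gene, was 8-fold higher in DG and Emx2 was higher by 1.71, and the anterior gene Six3 was higher in SVZ, at -3.51. Of the 30 lists, 23 were called, 17 as higher in DG and 6 as higher in SVZ, by camera with the preset correlation. The same test also called 4 to 23 lists in other splits of the libraries, which mixed the regions. With an estimated correlation camera called 0 (5 at an unadjusted p under 0.05), and fry, a rotation test of each list by itself, called 27. Where no second pair of counts is given, the counts adjusted over the list alone equalled those over all genes, as in 23 of the 30 lists.

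Library measures also differed between the regions. DG libraries held 36708583 ± 2745038 reads and SVZ libraries 31773849 ± 592293 (exact two-sided permutation test, p = 0.0159, adjusted p = 0.0212). Genes with at least 1 read numbered 14468 ± 5.29 in DG and 14422 ± 20.1 in SVZ (exact permutation p = 0.00794, the smallest this design can give, adjusted p = 0.0212). This count is out of the 14477 genes of a table that was already filtered on low counts, so it does not measure detection over the whole transcriptome. Mitochondrially encoded genes took 0.375 ± 0.0748% of reads in DG and 0.639 ± 0.157% in SVZ (exact permutation p = 0.0159, adjusted p = 0.0212). The 100 most abundant genes took 21.9 ± 1.01% and 22.9 ± 0.280%, a difference that did not pass (exact permutation p = 0.127, adjusted p = 0.127). The antisense gene with the largest overlap covers 46.7% of the exon bases of Bmp5, 23.4% of Ccnd1 and 18.3% of Fdft1. For Fzd5, Cryab and Slc6a20a the share is 17.8%, 17% and 13.8%, and the library kit does not mark the strand. Reads in the shared parts therefore cannot be told from those of the partner, and H2-K1 shares sequence with other histocompatibility genes.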

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

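In each group of libraries, the gap between the highest or lowest value and its nearest neighbour was divided by the group's range and compared with Dixon's 95% limit. Of 330 groups of values, 36 exceeded the limit where chance gives about 16.5. Of the tests weighed here, those on carry-over of unsorted cells, scaling, reporter-carrying vascular cells, dilution of neural RNA and dividing SVZ precursors were chosen after the results were seen.

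Library DG 2 exceeded the limit for 14 values. The ratios were 0.888 for Dlx6os1, 0.716 for Sp9, 0.795 for Dlx1, 0.836 for Dlx5, 0.887 for Meis2, 0.776 for Sp8, 0.733 for Chodl, 0.89 for Tiam2, 0.782 for Foxp2, 0.78 for Pbx3 and 0.746 for Dlx2, each higher in DG 2 than in the other DG libraries. Nes was also highest there (6.98 against 5.89 to 6.20, ratio 0.716), as were the means of the ventral list (3.88 against 1.31 to 1.80, ratio 0.807) and the neuroblast list (8.26 against 7.58 to 7.76, ratio 0.733).

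In SVZ 1, endothelial genes had a higher mean than in the other SVZ libraries (2.50 against 0.94 to 1.11, ratio 0.893) and astroglial genes a lower one (5.57 against 5.96 to 6.01, ratio 0.888). More genes had at least 1 read in SVZ 1 (14452 against 14410 to 14415, ratio 0.881). Slc6a20a (0.869), Slc22a8 (0.836), Sox2 (0.847), Notch3 (0.883), Wnt5a (0.895) and Gpr161 (0.859) were highest in that library within its group, and Aldoc (0.886) was lowest. DG 5 was lowest in its group for Anpep (0.715), Slc22a8 (0.807), Ebf1 (0.718), Slc6a13 (0.771) and Fzd5 (0.82). DG 3 had the highest mean of mature neuron genes (5.98 against 3.84 to 4.08, ratio 0.885), the highest Xdh (0.713) and the lowest Neurod1 (0.752). SVZ 3 held the 1 read of Nox3 in its group (ratio 1) and the lowest Eomes (0.85), SVZ 4 the lowest Smad2 (0.903) and SVZ 2 the highest mean of cell cycle genes (7.49 against 7.26 to 7.29, ratio 0.864).

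The first pattern weighed is the higher level of endothelial, pericyte and fibroblast genes in DG. Border macrophage, oligodendrocyte precursor and mature oligodendrocyte genes rose as well (medians 5.384, 3.55 and 1.53), but microglial genes had a median log2 fold change of 0.352 (95% bootstrap interval -0.763 to 0.749; -0.08 without SVZ 1, 0.64 without DG 2), far below the pericyte median of 5.95. This argues against a carry-over of all unsorted cell types alike, not against one of particular types. Scaling shifts all genes of a library alike, and the median of all genes was -0.075, which argues against scaling. The pericyte median with TMM was 6, but TMM factors of 0.96 to 1.03 could not have lowered it much, so that value decides nothing. Vascular cells of the DG that carry the nestin reporter may have entered the gate, but this cannot be told apart from other sources, because Nes itself was lower in DG (-0.951) and no library of reporter-negative or vessel-depleted cells was analysed here. A difference between the tissues in vessel supply, or in the cells that express the transgene, stays open and was not tested.

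The second pattern is the lower level of cell cycle and neuroblast genes in DG. Dilution of all neural RNA by RNA of vascular and other cells would lower astroglial genes as well. Their median was higher in DG by 1.968 (95% bootstrap interval 1.355 to 2.288), which argues against an equal dilution of all neural RNA. The list also holds genes of astrocytes, such as Gfap and Aldoc. Of its members 27 were higher in DG and 4 in SVZ, among these Sox2 (-1.11) and Nes (-0.95). Dilution of precursor RNA was not tested separately and stays open. A bias of GC content or transcript length is argued against by the cell cycle median after a loess fit on both, which was -1.76 (-1.885 to -1.635). A hypothesis that remains is a tissue difference in the share of dividing precursors and neuroblasts among reporter-positive cells, which the libraries may carry but which was not measured separately.

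The third pattern is the higher level of ventral lineage genes in DG 2. For each gene, the excess of DG 2 over the other DG libraries was taken as a share of the difference between SVZ and those libraries. Carry-over of whole SVZ material would bring ependymal genes along, and their median share was -0.895% (95% bootstrap interval -1.79 to 1.88) against 17.4% (15.1 to 19.5) for ventral genes, which argues against it. Neuroblast genes had a median share of 18.3% (15.8 to 23.4), so SVZ-type neuroblasts among the cells of DG 2 are a candidate explanation. The other DG libraries had neuroblast shares of -11.2 to -3.01%. DG 2 was among the libraries they were compared with, and its excess lowers these shares. They are therefore no independent baseline. Dividing SVZ precursors at the ventral share would raise cell cycle genes by as much, but their share was -13.6% (-18.5 to -4.09) in DG 2, with 12.2% the highest of 37 genes. The other DG libraries ranged from -6.32 to 12.1%, over 18.4 points. The upper bound of DG 2 raised by that range, 14.3%, stays below the ventral lower bound of 15.1%. That gap is small, and the bounds cover only the spread over genes within 1 library. DG 2 was again among the libraries that the others were compared with. Cell cycle genes were thus not raised in DG 2, but the comparison does not decide whether such precursors were present at that share. That share and a smaller one stay open, and how neuroblasts would have entered DG 2 was not tested.

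The regions were also compared with other splits of the 9 libraries into 5 and 4, of which 100 were drawn, the real one included. For genes higher in the group of 5, 1 split, the real one, reached the count of 4769 (higher in DG), and the highest other gave 3438. For genes higher in SVZ it was likewise 1 split, with 4873 against 3875. A share of 1 in 100 is the smallest that these draws can give. It makes chance an unlikely source of both counts but does not show what sets the groups apart. Both highest others came from the split that placed DG 2 with the SVZ libraries, in which 3875 genes were higher in the other DG libraries and 3438 were lower. For the number of gene lists called, 7 splits gave 23 or more, and the highest other gave 23, so chance is not excluded for that number. The other splits, which mixed the regions, called 4 to 23 lists, also where 0 genes were called. A call by camera with the preset correlation therefore does not by itself show that a list differs between the regions.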

How the results depend on the processing

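TMM scaling, prior counts of 0.5 and 5, a fit without the trend, other settings of the similarity and the setting without DG 2, DG 3 and SVZ 1 were chosen after seeing the data. Genes higher in DG numbered 4769 and ranged from 3790 (stricter filter, fewer genes tested) to 5008 (TMM), with 4522 to 4775 when 1 library was left out. Genes higher in SVZ numbered 4873 and ranged from 3732 (threshold of 0.01) to 4889 (prior count of 5), with 4448 to 4820 when 1 library was left out. A minimum log2 fold change of 1 left 3287 and 1792. Without DG 2, DG 3 and SVZ 1 the counts were 4322 and 4249, of which 4265 and 4079 genes were shared. Called lists numbered 23 and ranged from 21 to 24 without 1 library, with 22 under TMM or the stricter filter and 27 by fry, which asks another question. With an estimated correlation camera called 0 lists (5 at an unadjusted p under 0.05). The estimates for the 23 called lists ranged from 0.0232 (growth factor receptors) to 0.89 (mitochondrially encoded genes), all above the preset 0.01. They were 0.055 for the dorsal list, 0.315 for cell cycle, 0.542 for ventral, 0.613 for pericyte and 0.87 for ribosomal protein genes. The preset was thus far below many of the estimates, and the cause was not tested. The gap between the mean correlation within and between groups was 0.186 and rose to 0.267 under the stricter filter. The cause of that rise was not tested.

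The microglia list, never called, changed direction with the replicate block (adjusted p = 0.948) and without DG 2, DG 3 and SVZ 1 (adjusted p = 0.728), against 0.891 with all libraries, and also without DG 1, DG 3, DG 5 or SVZ 1 (0.273 to 0.997 over all libraries left out in turn). The choroid plexus list changed direction by fry (adjusted p = 0.506) and without DG 4 or SVZ 3 (0.679 to 0.975 over all libraries left out in turn); its members go both ways. Of the other list results 405 kept direction and call, 29 lost the call, most of them with an estimated correlation, and 6 gained it: oxidative phosphorylation without DG 5 and with the block (adjusted p = 0.0206), and synthesis of fatty acids and cholesterol, immediate early, Hedgehog and patterning genes by fry. For named genes, 2471 results kept direction and call, 14 lost the call and 0 reversed. Without DG 2, DG 3 and SVZ 1 the calls of Ccnd3, Igfbpl1, Gapdh, Eci2, Rbpj and Ifit2 were lost (adjusted p = 0.0554, 0.0878, 0.0625, 0.0528, 0.0718 and 0.0961), with fewer libraries in the fit.

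The labels number the libraries in both groups but do not say that the numbers pair them. Same-numbered libraries did not deviate together over all genes (correlations across genes -0.045, -0.17, 0.0073 and -0.11, and 0 best with their own number), and the main fit did not pair them. These correlations cannot show whether libraries share animals, since other spread, as of the ventral genes in DG 2, enters them too. In sex-linked genes DG 3 and SVZ 3 resembled each other (Xist at -0.18 and -0.13 log2 CPM), so pairing stays open. The replicate block gave 4513 genes higher in DG, 4273 higher in SVZ and 24 lists, and Tmem119 lost its call (adjusted p = 0.0555). DG exceeded SVZ by 311 genes with at least 10 reads and by 46.5 genes with every library thinned to the smallest total. The planned quasi-likelihood and DESeq2 tests were left out, since the design called for limma if log2 values were deposited; of tests on the recovered reads, limma-voom was run (4938 and 4490 genes). No test without the low-count filter was possible on a table already filtered. With 200 of the 14477 simulated genes changed, 16.4% of 1.5-fold changes were recovered. That share does not carry over to the real fit, where 66.6% of genes were called.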

Other observations

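Of these tests, the one on sex-linked genes and the choice of gene families were made after the results were seen, and the one on border macrophages was fixed before its genes were examined. Beyond the lists, 16 families defined by gene symbol were compared with all called genes by Fisher's exact test, adjusted over the families. For every family this test treats genes as independent, though all rest on the same 9 libraries. Its p-values therefore do not measure the spread between libraries. Endothelial and pericyte genes were higher in DG (medians 5.42 and 5.95), and those lists hold some members of the families. Collagen and laminin genes were mostly higher in DG: 19 of 26 collagen genes were higher in DG and 2 in SVZ (median log2 fold change 2.49, Fisher's exact adjusted p = 0.00033), as were 7 of 8 laminin genes and 0 in SVZ (median 3.51, adjusted p = 0.0091). Col4a1 and Lama4, of the vascular basement membrane, differed by 4.42 and 5.60 and the fibrillar collagen Col3a1 by 5.73, whereas Col8a2 and Col6a5 were lower (-3.98 and -5.20). Integrins, the receptors of matrix, were higher in DG for 13 of 21 genes and in SVZ for 2 (adjusted p = 0.00553), among them Itga1 (6.74). Solute carrier and ABC transporter genes leaned the same way, with 152 of 253 solute carriers higher in DG and 26 in SVZ (median 0.83, adjusted p = 4.54e-23) and 22 of 37 ABC transporters against 2 (median 0.68, adjusted p = 6.4e-05). Abcb1a, an efflux pump of the blood-brain barrier, differed by 6.61 (7.29 without SVZ 1). Potassium channel genes were higher in DG for 33 of 59 and in SVZ for 9 (median 1.21, adjusted p = 0.000387), and chemokine genes for 12 of 21 and 1 (median 2.43, adjusted p = 0.00292). Cadherins (40 and 18 of 83, adjusted p = 0.0055) and semaphorins with plexins (18 and 6 of 29, adjusted p = 0.0155) also leaned to DG, and ephrins with their receptors did not lean (7 and 7 of 17, adjusted p = 1).

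The families that leaned to SVZ were ribonucleoproteins, splicing factors, zinc finger proteins, kinesins, tubulins and ubiquitin-conjugating enzymes. They did so beside cell cycle and neuroblast genes lower in DG (medians -1.46 and -1.57) and endothelial and pericyte genes higher in DG (5.42 and 5.95). All 20 measured heterogeneous nuclear ribonucleoprotein genes were higher in SVZ (median -0.82, Fisher's exact adjusted p = 1.02e-05), and 8 of 11 serine and arginine rich splicing factor genes were, with 1 higher in DG (median -0.65, adjusted p = 0.0417). Of 355 zinc finger protein genes, 199 were higher in SVZ and 24 in DG (median -0.48, adjusted p = 2.19e-34). Kinesin genes were higher in SVZ for 24 of 39 and in DG for 5 (median -0.80, adjusted p = 0.00125), with the spindle motor Kif11, of the cell cycle list, at -1.73. Tubulin genes were higher in SVZ for 13 of 18 and in DG for 2 (median -0.61, adjusted p = 0.0091), with Tubb3, of the neuroblast list, at -2.28, Tubb5 at -1.67 and Tuba4a at 1.98. Ubiquitin-conjugating enzymes were higher in SVZ for 20 of 33 and in DG for 4 (median -0.43, adjusted p = 0.00292).

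Mrc1 and Pf4 were higher in DG while the microglia list was not called. A hypothesis is that border-associated macrophages, which lie along vessels and in the meninges, may be among the DG cells. In a further list of 16 genes of these cells, 16 were higher in DG, with a median log2 fold change of 5.384 (95% bootstrap interval 4.325 to 6.116), and the value stayed the same with the gene that had 1 to 3 SVZ reads at its bound. Slc40a1, the most abundant, stood at 7.78 in DG and 3.45 in SVZ, Colec12 at 6.36 and 0.97, and Cd209f at 5.03 and -1.05. Endothelial, pericyte and fibroblast genes were higher in DG as well (medians 5.42, 5.95 and 4.72). Whether cells other than macrophages gave reads of the 16 genes was not tested. A gate on fluorescence would remove such cells unless they carry the reporter, adhere to cells that do or are fluorescent by themselves, and none of these was tested.

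Sex-linked genes differed between libraries within both tissues. In DG 3 and SVZ 3 the X inactivation transcript Xist stood at -0.18 and -0.13 log2 CPM and the Y-linked Ddx3y at 7.10 and 6.59, in DG 5 at 5.57 and -1.88, and in the other 6 libraries both were present, as in DG 1 with 5.01 and 5.81. These 6 libraries therefore held RNA of both sexes, as a pool of animals would and 1 animal would not. Whether same-numbered DG and SVZ libraries come from the same pools or animals stays open. Of the 24 ways to match 4 DG with 4 SVZ numbers, 1, that of the labels, gave a squared distance as small as 8.55, but the resemblance of DG 3 and SVZ 3 prompted the test and favours the 6 matchings that keep them together. Among those 6 the share cannot go below 0.167, and the next distance was 8.81.

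Ttr, the most abundant transcript of the choroid plexus, stood at 7.48 log2 CPM in DG 2, 4.61 in DG 5, 2.04 in DG 1, 1.51 in DG 3 and 1.46 in DG 4, and at 0.56 to 1.62 in the SVZ libraries.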
